A study of Mus musculus with 24 samples.

How the data were processed

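RNA from mouse splenic B cells was sequenced in 24 libraries, 3 in each of 8 groups. Per the labels' protocols the mice were C57BL/6, B cells were isolated from the spleen with immunomagnetic beads, and libraries were made from total RNA with the TruSeq RNA v2 kit. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with STAR 2.4.0.1. The deposited table holds raw counts of reads per gene for the 24 libraries under numeric Entrez gene identifiers, with no scaling and with genes at 0 kept. The program that counted the reads, its annotation and its strand setting are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart, and levels of near-identical copies, such as Hspa1a and Hspa1b or immunoglobulin V segments, are uncertain where the counting could split them.

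The table holds 27179 identifiers. A RefSeq annotation of the same assembly gave a symbol for 25275 of them, and coordinates are 1-based in GRCm38.p6, the assembly that mm10 names. The 1904 identifiers without a match held between 0.522% and 1.06% of the counts of a library and stayed in the tests under their numbers. A count of 0 in all 24 libraries was found for 1251 genes. Totals ran from 28496148 to 78124927 counts per library. Replicates differed far beyond counting error, with at least 35.4 times the chi-square per degree of freedom that counting error alone gives.

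Each comparison used the edgeR quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, filterByExpr at its minimum count of 10, robust estimation and 1 mean per group. Adjusted p-values are Benjamini-Hochberg values over the genes tested in that comparison, and a gene is called at an adjusted p under 0.05. Libraries entered 2 fits of 12. The first held the 4 groups of 4-month mice. The second held the 15-month wild type group and the 3 groups of chronic lymphocytic leukaemia (CLL). Comparisons within a fit share its estimate of spread. Levels of groups are mean CPM values on TMM-scaled library sizes. CPM values of single libraries, and sums over basophil or receptor genes, are counts over the plain library total without that scaling. Where a standard error (SE) is printed with a log2 fold change, it is the absolute change divided by the square root of the F statistic. The labels do not say whether replicates are separate mice, so p-values measure only the spread between samples. Labels also give CLL Dnmt3a fl/+ an age of 8 months, which no control group shares.

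Lists of genes, 29 in number and with 600 of their 602 members in the table, were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1), with Benjamini-Hochberg adjustment over the 29 lists of a comparison. Camera compares a list with all other genes, and fry asks whether its members moved, on balance, in 1 direction. For each library, the share of the most counted immunoglobulin heavy chain V segment among all 120 Ighv segments, and likewise among 103 Igkv segments, was compared by an exact two-sided permutation test. Intervals on such shares are 95% Clopper-Pearson intervals and cover counting error only. For pairs of CLL comparisons with the same controls, 20 simulations of unchanged groups estimated the covariance and correlation that shared controls bring. They used the spread pooled over all 4 groups of that fit.

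Gene lists, comparisons, tests and the alternatives of the first plan were fixed before the data were examined. The text names Dnmt3a, the 6 largest rises and 6 largest falls per comparison, up to 4 members with the smallest adjusted p of each list described, a panel of 18 genes, sex-linked genes and leading V segments. The largest changes were taken among called genes with an average log2 CPM of at least 3 and groups that did not overlap, without predicted, immunoglobulin and T cell receptor genes. A symbol that stands outside this rule is said to be chosen after its values were seen.

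Alternatives were other scaling factors, scaling without immunoglobulin genes, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, other sets of libraries in the fit, the replicate number as a block, each library left out, a minimum log2 fold change of 1, and 4-month wild type groups as controls of CLL. Of the tests, only edgeR, camera and fry were first run on simulated data, with the real means and library sizes and genes drawn independently. In these, edgeR recovered 47% of genes changed 2-fold and 73% of genes changed 4-fold for B1, 45% and 70% for B2, and 1% and 36% for CLL Dnmt3a fl/fl against wild type. Recovery was 3% and 36% for CLL Dnmt3a fl/+, 4% and 32% for CLL MDR fl/fl, and 0% and 31% for the comparison of the Dnmt3a CLL groups with each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main tests.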

Results

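Gene expression was measured by RNA sequencing in splenic B cells of mice with 1 or both alleles of Dnmt3a, a DNA methyltransferase, flanked by loxP sites (fl/+ and fl/fl), of mice labelled MDR fl/fl, and of wild type mice. MDR is understood here as the minimal deleted region, a locus with Dleu2 and the microRNAs miR-15a and miR-16-1 whose loss gives mice a CLL-like disease. The 24 libraries form 8 groups of 3. Mice of 4 months gave B1 wild type, B1 Dnmt3a fl/fl, B2 wild type and B2 Dnmt3a fl/fl. The genotype of the control groups is labelled wild type, while their titles name Cre (CD19-Cre at 15 months), so these controls are taken to carry the recombinase. B1 and B2 are the names in the titles, and no sort of these subsets is described. Mice of 15 months gave wild type B cells, CLL Dnmt3a fl/fl and CLL MDR fl/fl, and mice of 8 months gave CLL Dnmt3a fl/+. B2 wild type replicate 3 had the lowest total, 28496148 counts, and the other B1 and B2 wild type libraries had 35416773 to 43704562. Totals ran from 35772935 to 68681335 in B1 and B2 Dnmt3a fl/fl and from 46065938 to 78124927 in the 15-month and CLL groups. Levels below are mean CPM with n = 3 libraries, ± SD where printed. Log2 fold changes rest on 3 libraries in each group, with ± SE and the edgeR adjusted p where these are printed.

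Dnmt3a (gene 13435, chromosome 12, 3801559 to 3914443) was the targeted gene. Its level was 37.0 ± 3.1 CPM in B1 wild type and 23.0 ± 3.3 in B1 Dnmt3a fl/fl, and 46.0 ± 4.6 in B2 wild type and 24.5 ± 2.5 in B2 Dnmt3a fl/fl. The log2 fold change was −0.69 ± 0.142 in B1 (adjusted p = 0.00642) and −0.91 ± 0.142 in B2 (adjusted p = 0.0681). Averaged over B1 and B2, Dnmt3a fell by 0.80 ± 0.1 (adjusted p = 0.00161). All 6 Dnmt3a fl/fl libraries of 4-month mice lay below their 3 wild type libraries. In the older mice Dnmt3a stood at 52.4 ± 4.6 CPM in wild type, 52.7 ± 1.6 in CLL MDR fl/fl, 34.6 ± 10.4 in CLL Dnmt3a fl/+ and 32.0 ± 11 in CLL Dnmt3a fl/fl. Against 15-month wild type neither Dnmt3a CLL group passed, with −0.71 ± 0.257 (adjusted p = 0.116) for fl/fl and −0.60 (adjusted p = 0.157) for fl/+. Without CLL Dnmt3a fl/fl replicate 3 the fl/fl value was −1.03 (adjusted p = 0.0352). Gene totals include exons outside the floxed part, so a remaining level does not give the share of undeleted alleles.

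**Figure D1:**
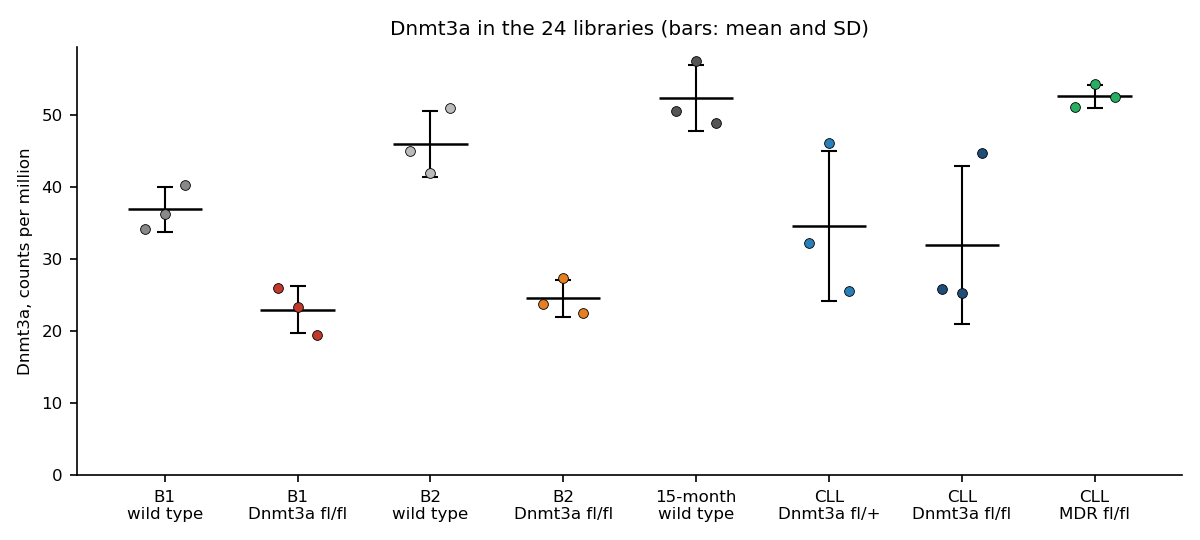
Dnmt3a level in CPM (vertical axis) for each of the 24 libraries by group, points for libraries and bars for group mean and SD. B1 Dnmt3a fl/fl averaged 23.0 CPM against 37.0 in B1 wild type, and B2 Dnmt3a fl/fl 24.5 against 46.0.

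The first comparison asked what loss of Dnmt3a changes in the preleukaemic libraries titled B1. Jchain, which joins polymeric immunoglobulin, rose from 106 ± 14.5 to 867 ± 273 CPM (log2 fold change 3.03 ± 0.48, adjusted p = 0.00194). Fcer1g, the Fc receptor gamma chain, rose from 10.3 ± 1.44 to 93.7 ± 31.3 CPM (3.19 ± 0.319, adjusted p = 8.81e-05), and the activation marker Cd69 from 24.2 ± 3.56 to 118 ± 34.6 CPM (2.29 ± 0.194, adjusted p = 3.37e-05). The transcription factor Pax5, which holds B cell identity, fell (−2.02 ± 0.135, adjusted p = 7.99e-06). Lower too were Bhlhe40, a transcription factor, from 59.1 ± 17.6 to 11 ± 4.6 CPM (−2.43 ± 0.305) and Ercc2, a DNA repair helicase, from 14.5 ± 2.59 to 1.58 ± 0.509 CPM (−3.21 ± 0.262). The heat shock gene Hspa1a showed the largest rise, 4.39 ± 0.929, at a level that varied widely between libraries (48.6 ± 37.2 CPM), and reads of its near-identical copy Hspa1b are not known to be kept apart.

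Among gene groups in B1, 13 of 53 MYC targets fell, none rose and 40 did not pass (2 up and 16 down adjusted over the list alone). Mybbp1a at −0.97 ± 0.115 and Ipo4 at −1.05 were among them. Myc itself stood at 533 ± 102 and 616 ± 29.2 CPM without a call. Camera placed the list lower (adjusted p = 0.0276; adjusted p = 0.648 with an estimated correlation). Respiratory chain genes went the other way: 11 of 34 rose, 2 fell and 21 did not pass (18 up and 3 down adjusted over the list alone). Sdhb (0.49 ± 0.0845) and Uqcrc1 (0.43 ± 0.089) were among the former, with camera adjusted p = 2.85e-05 and adjusted p = 0.628 with an estimated correlation. Of 30 genes of B cell receptor signalling 11 fell, 3 rose and 16 did not pass (3 up and 12 down adjusted over the list alone). Lower members were Inpp5d, a phosphatase that limits signalling (−0.95 ± 0.143), the exchange factor Vav2 (−1.01 ± 0.171) and the lipase Plcg2 (−0.68 ± 0.12). That list had camera adjusted p = 0.0276 and adjusted p = 0.648 with an estimated correlation. Of 22 B lineage genes 6 fell, including Spib (−1.18 ± 0.135) and Ciita (−1.06 ± 0.142), 2 rose and 14 did not pass (4 up and 8 down adjusted over the list alone; camera adjusted p = 0.0437, adjusted p = 0.628 with an estimated correlation). Follicular and marginal zone markers had 6 of 16 lower, 1 higher and 9 not past the threshold (2 up and 8 down adjusted over the list alone). The low-affinity IgE receptor Fcer2a fell from 11.2 ± 0.717 to 4.51 ± 1.18 CPM (camera adjusted p = 0.0281, adjusted p = 0.628 with an estimated correlation). In the Notch pathway 6 of 29 fell, 1 rose and 22 did not pass (1 up and 8 down adjusted over the list alone). Lfng, which modifies Notch receptors, was at −1.50 ± 0.16 and Dtx2 at −1.45 ± 0.21, and camera did not call the list (adjusted p = 0.0901). Markers of natural killer cells moved with the genotype, with 4 of 11 lower, among them Ccl5 (−1.63 ± 0.33), 0 higher and 7 not past (0 up and 6 down adjusted over the list alone; camera adjusted p = 0.000665, adjusted p = 0.628 with an estimated correlation).

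The edgeR test called 2261 of 15459 genes in B1, 757 higher and 1504 lower. In 32.6% of tested genes the groups did not overlap, where chance gives 10%. The count was 1377 without B1 wild type replicate 1, 1357 without B1 Dnmt3a fl/fl replicate 2 and 1328 without B1 Dnmt3a fl/fl replicate 3, the only B1 library with Xist (106 CPM) in place of Y-linked transcripts. It was 1370 with the B1 groups fitted alone, 1435 without a filter and 783 in a fit of all 24 libraries.

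The same question was put to the libraries titled B2. The transcription cofactor Lbh (chromosome 17, 72918305 to 72941946) rose from 183 ± 8.17 to 460 ± 30 CPM (1.33 ± 0.111, adjusted p = 0.000307). Ide, a protease that degrades insulin (chromosome 19, 37268743 to 37334544), fell from 109 ± 7.46 to 57.3 ± 1.58 CPM (−0.92 ± 0.114, adjusted p = 0.0141). Markers of T cells stood lower as a list without a called member: the 20 measured had a median log2 fold change of −2.06, with Cd8b1 at −2.92 ± 0.562 (adjusted p = 0.172) and Cd3g at −2.78 ± 0.546 (adjusted p = 0.172). Adjusted over the list alone 14 of them were lower and 1 higher (camera adjusted p = 9.45e-14, adjusted p = 0.2 with an estimated correlation). Neutrophil markers had a median of −1.76 and erythroid markers of 1.53, with camera adjusted p = 1.62e-05 and 0.00295, and adjusted p = 0.283 and adjusted p = 0.543 with an estimated correlation. Immediate early and heat shock genes had 0 called members, 5 lower and 0 higher adjusted over the list alone, with Hspa1a at −4.71 ± 0.937 (adjusted p = 0.194; camera adjusted p = 0.00528, adjusted p = 0.339 with an estimated correlation).

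The B2 test called 2 of 15459 genes, and 1812 had an unadjusted p under 0.05. The DESeq2 Wald test called 196 and limma-voom 2. The count was 1 without B2 wild type replicate 1, 13 without B2 wild type replicate 3, whose median count per gene was 36 against 15 and 13 in its fellows, and 13 without B2 Dnmt3a fl/fl replicate 2. Ide was not called in 4 of the 6 fits without 1 library, with adjusted p up to 0.103 without B2 Dnmt3a fl/fl replicate 3.

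Averaged over B1 and B2, Dnmt3a fl/fl libraries had lower Fam43a (−1.10 ± 0.122, adjusted p = 0.000719), lower Tubb2b, a beta tubulin (−1.08 ± 0.118), and lower Slc35c1, the GDP-fucose transporter of the Golgi (−0.96 ± 0.0973, adjusted p = 0.000575). These falls were larger in B1 than in B2 by the test of the difference, with Fam43a at −2.03 in B1 and −0.17 in B2, Tubb2b at −1.67 and −0.49, and Slc35c1 at −1.57 and −0.36. The serpin Serpinb6b rose (1.31 ± 0.185), as did Smim40 (1.32 ± 0.177) and Echdc3 (0.82 ± 0.123). The 2 Notch regulators Lfng (−0.63 ± 0.111) and Dtx2 (−0.87 ± 0.145) fell, among 4 lower, 0 higher and 25 not past of 29 Notch genes (1 up and 4 down adjusted over the list alone). Their falls lay in B1, with Lfng at −1.50 in B1 and 0.25 in B2 (adjusted p of the difference 0.00114) and Dtx2 at −1.45 and −0.28. That list was not called by camera (adjusted p = 0.0859). T cell markers fell in 8 of 20, with 0 higher and 12 not past (1 up and 13 down adjusted over the list alone). Among them were Cd8b1 (−2.25 ± 0.39) and the adaptor Lat (−1.60 ± 0.295), with camera adjusted p = 6.78e-07 and adjusted p = 0.313 with an estimated correlation. Respiratory chain genes had 1 of 34 higher, Sdhb at 0.30 ± 0.0597, 0 lower and 33 not past (9 up and 0 down adjusted over the list alone; camera adjusted p = 1.11e-05, adjusted p = 0.589 with an estimated correlation).

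The mean contrast called 1042 genes, 359 higher and 683 lower, 124 of them at least 2-fold. Without 1 library the count was 630 (B2 wild type replicate 2), 499 (B1 Dnmt3a fl/fl replicate 2), 512 (B1 Dnmt3a fl/fl replicate 3), 429, 588 and 260 (B2 Dnmt3a fl/fl replicates 1, 2 and 3). Sdhb was not called without B2 Dnmt3a fl/fl replicate 3 (adjusted p = 0.0601). The count was 208 without the pair of B2 libraries with broad background, where Lat was not called either (adjusted p = 0.0545).

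The difference between the genotype effects in B1 and B2 was itself tested. Lbh fell in B1 (−0.68) and rose in B2 (1.33), a difference of −2.01 (adjusted p = 0.000129). Pax5 was −2.02 in B1 and 0.11 in B2 (difference −2.13, adjusted p = 0.000153). Cd69 was 2.29 and −0.04 (difference 2.33, adjusted p = 0.000545), and Fcer2a was −1.32 and 0.75 (difference −2.07, adjusted p = 0.00245). MYC targets had 8 of 53 lower in the difference, 0 higher and 45 not past (0 up and 14 down adjusted over the list alone; camera adjusted p = 0.00181, adjusted p = 0.599 with an estimated correlation). Immediate early and heat shock genes had 5 of 20 higher, 0 lower and 15 not past (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0246, adjusted p = 0.599 with an estimated correlation). The test called 856 genes, 112 higher and 744 lower in B1 relative to B2. Upper-quartile scaling put 23.9% of its calls higher in place of 13.1%. The count was 543 without B1 Dnmt3a fl/fl replicate 3, and 507 and 477 without B2 Dnmt3a fl/fl replicates 1 and 2. It was 363 with sex as a term and 232 in a fit of all 24 libraries.

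B1 and B2 wild type libraries were compared to show what the titles separate. Zbtb32, a transcription factor of B1 cells (chromosome 7, 30589680 to 30602819), was at 691 ± 82.2 CPM in B1 and 2.67 ± 0.56 in B2 (8.02 ± 0.272, adjusted p = 7.85e-10). Fcer2a (chromosome 8, 3680280 to 3694174) was at 11.2 ± 0.717 and 1303 ± 406 CPM (−6.86 ± 0.263, adjusted p = 1.66e-09). Myc was higher in B1 (533 ± 102 against 174 ± 29.7 CPM; 1.61 ± 0.155, adjusted p = 3.89e-06), as were Cd5 (30 ± 8.5 against 5.01 ± 4.59 CPM; 2.59 ± 0.486) and the proliferation marker Mki67 (2.19 ± 0.381). All 14 B1 cell markers measured were higher in B1 (14 up and 0 down adjusted over the list alone), among them Plscr1 (4.94 ± 0.163). The call held with an estimated correlation (camera adjusted p = 9.88e-12, adjusted p = 0.0325 with an estimated correlation). Of 16 follicular and marginal zone markers 13 were lower in B1, 1 higher and 2 not past (1 up and 13 down adjusted over the list alone). The complement receptor Cr2 (−6.20 ± 0.264) and Ighd (−4.36 ± 0.176) were lower, and that call also held (camera adjusted p = 3.22e-09, adjusted p = 0.0325 with an estimated correlation). Cell cycle genes were higher in 31 of 38, lower in 1 and not past in 6 (32 up and 1 down adjusted over the list alone; camera adjusted p = 1.29e-08, adjusted p = 0.449 with an estimated correlation). Notch genes were lower in 13 of 29, higher in 4 and not past in 12 (4 up and 16 down adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.0824 with an estimated correlation), with Dtx1 at −2.99 ± 0.255 and Nrarp at −3.85 ± 0.658. All 10 platelet markers were lower in B1, with Ppbp at −8.11 ± 0.656 (0 up and 10 down adjusted over the list alone; camera adjusted p = 4.61e-07, adjusted p = 0.0824 with an estimated correlation). The test called 7142 genes, 3538 higher and 3604 lower.

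The CLL comparisons asked how leukaemic B cells differ from wild type B cells of 15 months. In CLL Dnmt3a fl/fl the surface marker Cd5 (chromosome 19, 10718107 to 10739026) rose from 2.72 ± 1.13 to 65.3 ± 24.8 CPM (4.59 ± 0.623, adjusted p = 0.00385). Myc (chromosome 15, 61985341 to 61990361) rose from 174 ± 42.1 to 483 ± 53.9 CPM (1.47 ± 0.269, adjusted p = 0.0122). Rflnb, a regulator of filamin, fell from 84.8 ± 26.7 to 0.337 ± 0.137 CPM (−7.99 ± 0.549, adjusted p = 0.00028). The kinase Lrrk2 fell from 170 ± 26.5 to 1.03 ± 0.708 CPM (−7.40 ± 0.88), and Fcer2a from 1110 ± 290 to 11.4 ± 7.04 CPM (−6.61 ± 1.37, adjusted p = 0.0211). B1 cell markers rose in 5 of 14 with 0 lower and 9 not past (9 up and 0 down adjusted over the list alone). The tetraspanin Cd9 (2.60 ± 0.356) and the transcription factor Arid3a (2.82 ± 0.44) rose, and camera gave adjusted p = 3.3e-09 and adjusted p = 0.32 with an estimated correlation. Follicular and marginal zone markers fell in 5 of 16 with 0 higher and 11 not past (0 up and 9 down adjusted over the list alone), such as Bach2, a repressor of plasma cell fate (−3.15 ± 0.52; camera adjusted p = 5.39e-05, adjusted p = 0.32 with an estimated correlation). Of 23 plasma cell genes 6 rose, 0 fell and 17 did not pass (16 up and 0 down adjusted over the list alone). Creld2, a chaperone, was at 2.85 ± 0.476 and Prdm1, the plasma cell regulator, at 3.005 ± 0.598 (camera adjusted p = 2.97e-10, adjusted p = 0.32 with an estimated correlation). Interferon response genes fell in 6 of 30 with 0 higher and 24 not past (0 up and 13 down adjusted over the list alone; camera adjusted p = 2.75e-06, adjusted p = 0.242 with an estimated correlation). Cd200r3, a receptor of basophils and mast cells, showed the largest rise (8.76 ± 2.15, adjusted p = 0.038), at 126 CPM in CLL Dnmt3a fl/fl replicate 3 and at 4.44 and 1.89 CPM in replicates 1 and 2. The sum of 7 other basophil and mast cell genes was 752 CPM in replicate 3. Macrophage markers rose in 2 of 20 with 0 lower and 18 not past (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.000235, adjusted p = 0.423 with an estimated correlation).

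The test called 1072 of 16131 genes in CLL Dnmt3a fl/fl, 500 higher and 572 lower. The count was 293 and 280 without CLL Dnmt3a fl/fl replicates 1 and 2, 277, 328 and 355 without 15-month wild type replicates 1, 2 and 3, and 2605 with the DESeq2 Wald test. In at least 1 of these fits Myc (highest adjusted p = 0.0527, without wild type replicate 2 or 3), Fcer2a (0.0891, without CLL Dnmt3a fl/fl replicate 2), Prdm1 (0.0819, without wild type replicate 1) and Cd200r3 (0.135, without wild type replicate 2) lost their call. Against B1 wild type of 4 months Myc was −0.10, Fcer2a 0.0554, Rflnb 0.84 and Cd9 −0.12.

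In CLL Dnmt3a fl/+, the group of 8-month mice, Cd5 rose to 53.3 ± 12.2 CPM (4.29 ± 0.614), Myc to 517 ± 52.0 CPM (1.57 ± 0.27, adjusted p = 0.00616) and Trim40, a ubiquitin ligase, by 6.25 ± 0.888 (adjusted p = 0.00299). The chemokine receptor Ccr6 fell (−7.89 ± 1.39), as did Rflnb (−8.50 ± 0.562) and Klf2, a regulator of lymphocyte quiescence and migration (−4.16 ± 0.571). Lef1, a transcription factor of the Wnt pathway (chromosome 3, 131110297 to 131224357), fell from 7.81 ± 4.96 to 0.277 CPM (−4.80 ± 0.737, adjusted p = 0.00369). MYC targets rose in 12 of 53, fell in 0 and did not pass in 41 (21 up and 1 down adjusted over the list alone). Ung rose (1.88 ± 0.289), with camera adjusted p = 1.23e-08 and adjusted p = 0.51 with an estimated correlation. Cell cycle genes rose in 4 of 38, fell in 0 and did not pass in 34 (11 up and 0 down adjusted over the list alone; camera adjusted p = 1.51e-08, adjusted p = 0.606 with an estimated correlation). B1 cell markers rose in 9 of 14, fell in 0 and did not pass in 5 (12 up and 0 down adjusted over the list alone). Spn (2.55) and Cd9 (2.31) were among them, with camera adjusted p = 1.51e-08 and adjusted p = 0.51 with an estimated correlation. Among 19 TP53 targets 5 rose, 2 fell and 12 did not pass (7 up and 2 down adjusted over the list alone). The cell cycle inhibitor Cdkn1a was at 2.78 ± 0.405 and Phlda3, an inhibitor of AKT, at 4.72 ± 0.608, and camera did not call the list (adjusted p = 0.0724). Cyp11a1, the first enzyme of steroid hormone synthesis, rose from 2.15 to 403 ± 155 CPM (7.56 ± 1.67, adjusted p = 0.0194).

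The test called 1728 genes in CLL Dnmt3a fl/+, 841 higher and 887 lower. The count was 812 and 909 without CLL Dnmt3a fl/+ replicates 1 and 3 and 594, 665 and 717 without 15-month wild type replicates 1, 2 and 3. Without any 1 of these wild type libraries Cyp11a1 was not called (adjusted p up to 0.0853, without replicate 1). Rflnb was 0.34 and Cd9 −0.40 against B1 wild type of 4 months, and age cannot be separated from disease in this group.

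In CLL MDR fl/fl, Dleu2 (chromosome 14, 61602836 to 61682373), a noncoding RNA of the region named in the title, fell from 14.4 ± 0.702 to 1.69 ± 0.298 CPM (−3.10 ± 0.353, adjusted p = 0.00313). Of 8 genes of that region measured 2 fell, 1 rose and 5 did not pass (3 up and 2 down adjusted over the list alone; camera adjusted p = 0.779). Lef1 fell to 0.345 CPM (−4.49 ± 0.724), Rflnb fell (−7.98 ± 0.547), and Lgals1, a lectin, rose (4.14). Of 19 TP53 targets 4 rose, 0 fell and 15 did not pass (8 up and 1 down adjusted over the list alone). Cdkn1a (3.70 ± 0.421) and Bbc3, which drives apoptosis (2.68 ± 0.314), rose, with camera adjusted p = 0.000514 and adjusted p = 0.218 with an estimated correlation. Among listed targets of miR-15 and miR-16, 4 of 14 rose, 1 fell and 9 did not pass (5 up and 1 down adjusted over the list alone). The kinases Wee1 (2.49) and Chek1 (2.44) rose, and camera did not call the list (adjusted p = 0.178). MYC targets rose in 7 of 53, fell in 0 and did not pass in 46 (20 up and 0 down adjusted over the list alone; camera adjusted p = 2.27e-11, adjusted p = 0.316 with an estimated correlation). Cell cycle genes rose in 7 of 38 with 0 lower and 31 not past (33 up and 0 down adjusted over the list alone; camera adjusted p = 1.28e-12, adjusted p = 0.479 with an estimated correlation). Follicular and marginal zone markers fell in 7 of 16 with 0 higher and 9 not past (0 up and 8 down adjusted over the list alone; camera adjusted p = 7.41e-08, adjusted p = 0.218 with an estimated correlation). Platelet markers were lower in 2 of 10 (camera adjusted p = 0.000715, adjusted p = 0.521 with an estimated correlation).

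The test called 991 genes in CLL MDR fl/fl, 568 higher and 423 lower. The count was 99, 222 and 110 without 15-month wild type replicates 1, 2 and 3, 491 and 1491 without CLL MDR fl/fl replicates 1 and 2, and 175 with these groups fitted alone. More of the calls were lower than higher with limma-voom (398 higher and 534 lower), with the groups fitted alone (40% higher) and without wild type replicate 1 (43 and 56), 2 (100 and 122) or 3 (49 and 61). Wee1 and Chek1 lost their call without any 1 wild type library (highest adjusted p = 0.0869 and 0.0976, both without replicate 3). Compared with B1 wild type of 4 months Rflnb was 0.85 and Lgals1 −0.52.

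Taking the mean of the 3 CLL groups against 15-month wild type, Myc rose (1.46 ± 0.237, adjusted p = 0.00422), as did Cd5 (3.59 ± 0.556). Fcer2a (−6.13 ± 0.836), Lrrk2 (−6.11 ± 0.519) and Rflnb (−8.16 ± 0.338, adjusted p = 1.66e-06) fell. B1 cell markers rose in 8 of 14 with 0 lower and 6 not past (12 up and 0 down adjusted over the list alone). Follicular and marginal zone markers fell in 9 of 16 with 0 higher and 7 not past (0 up and 9 down adjusted over the list alone). Camera gave adjusted p = 8.54e-09 and 2.33e-06 for these lists, and adjusted p = 0.277 with an estimated correlation for both. MYC targets rose in 16 of 53 with 0 lower and 37 not past (21 up and 0 down adjusted over the list alone). Srm (1.12) and Ung (1.41) rose, with camera adjusted p = 2.83e-10 and adjusted p = 0.277 with an estimated correlation. Interferon response genes fell in 9 of 30 with 0 higher and 21 not past (0 up and 13 down adjusted over the list alone; camera adjusted p = 0.00029, adjusted p = 0.277 with an estimated correlation). Human CLL markers went both ways, with 5 of 20 higher, such as Cd5 and Ctla4 (4.45), 4 lower, such as Lef1 (−2.66 ± 0.467) and Fcer2a, and 11 not past (camera adjusted p = 0.452). The Lef1 mean joins groups that moved apart, with 0.277 CPM in CLL Dnmt3a fl/+ and 0.345 in CLL MDR fl/fl but 19.3 ± 11.7 in CLL Dnmt3a fl/fl, against 7.81 ± 4.96 in wild type. Genes of chromosome 15 stood higher as a whole. The median log2 ratio to wild type over 268 genes was 0.43 ± 0.18 (SD, n = 9) in CLL, against −0.0063 ± 0.023 (n = 3) in wild type. It ran from 0.047 in CLL MDR fl/fl replicate 2 to 0.58 in CLL Dnmt3a fl/+ replicate 1. A two-sided permutation test gave p = 0.00455, the smallest these numbers allow (adjusted p = 0.091 over 20 chromosomes). With 1 chromosome shifted alone the adjusted p cannot fall below that value. Each CLL library was set against the mean of all 3 wild type libraries, each wild type library against the other 2. The libraries are thus not exchangeable, so this p is not exact and can be too low. Chromosome 15 was singled out after its values were seen.

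The mean contrast called 2101 genes, 921 higher and 1180 lower, and 1860 when genes of chromosomes 15 and 17 were left out. The DESeq2 Wald test called more higher than lower (2019 and 1619). It was 661, 809 and 696 without 15-month wild type replicates 1, 2 and 3 and 3314 without CLL MDR fl/fl replicate 2. Without any 1 wild type library Ctla4 lost its call (adjusted p up to 0.129, without replicate 1), as did Lef1 without wild type replicate 3 (adjusted p = 0.0528).

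**Figure D2:**
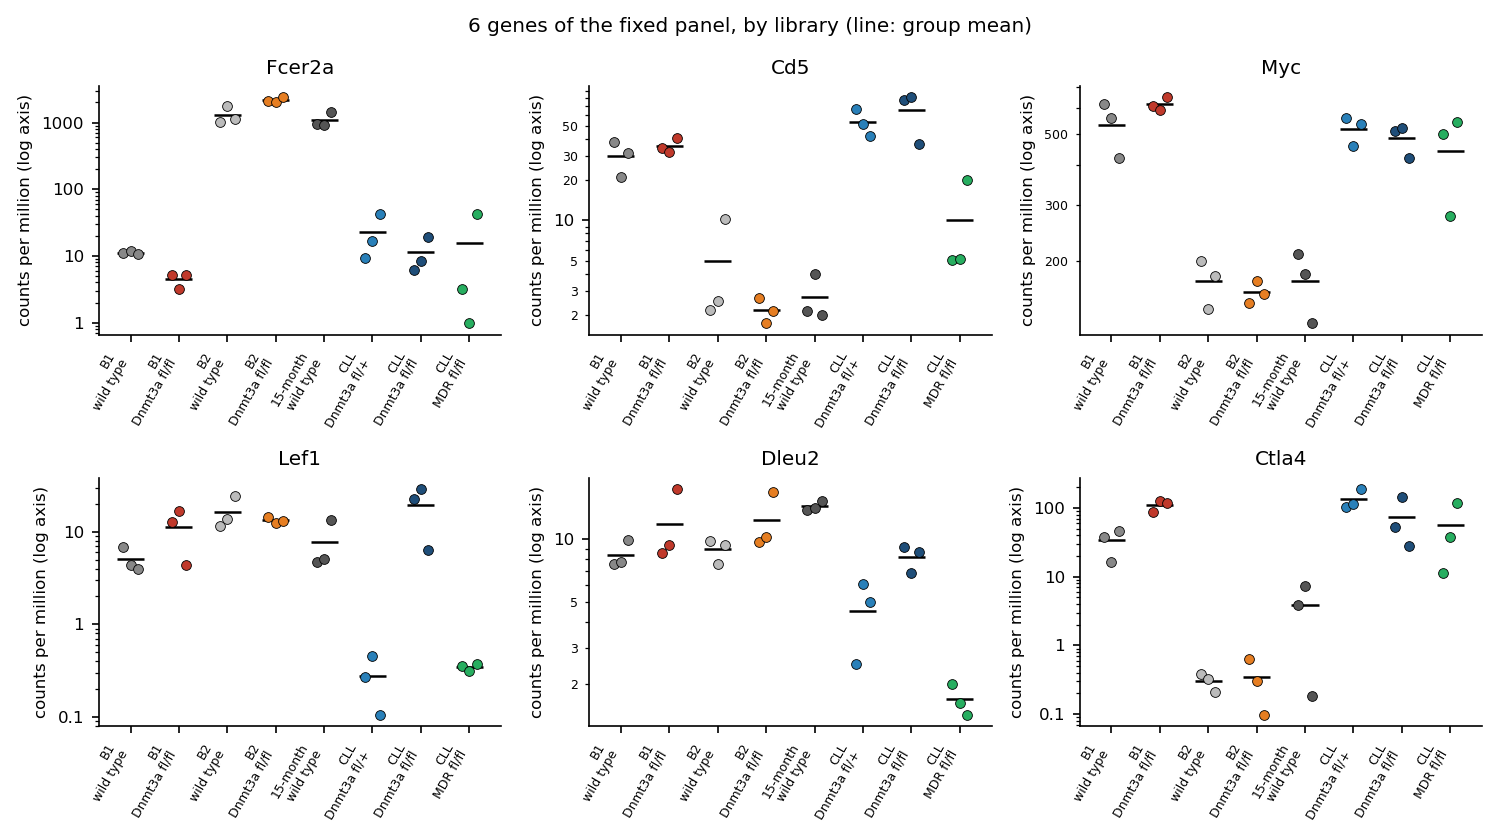
Level in CPM on log axes (vertical) of 6 genes of the fixed panel in each of the 24 libraries by group, points for libraries and lines for group means. Fcer2a averaged 1110 CPM in 15-month wild type and 11.4 in CLL Dnmt3a fl/fl, and Myc 174 and 483.

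**Figure D3:**
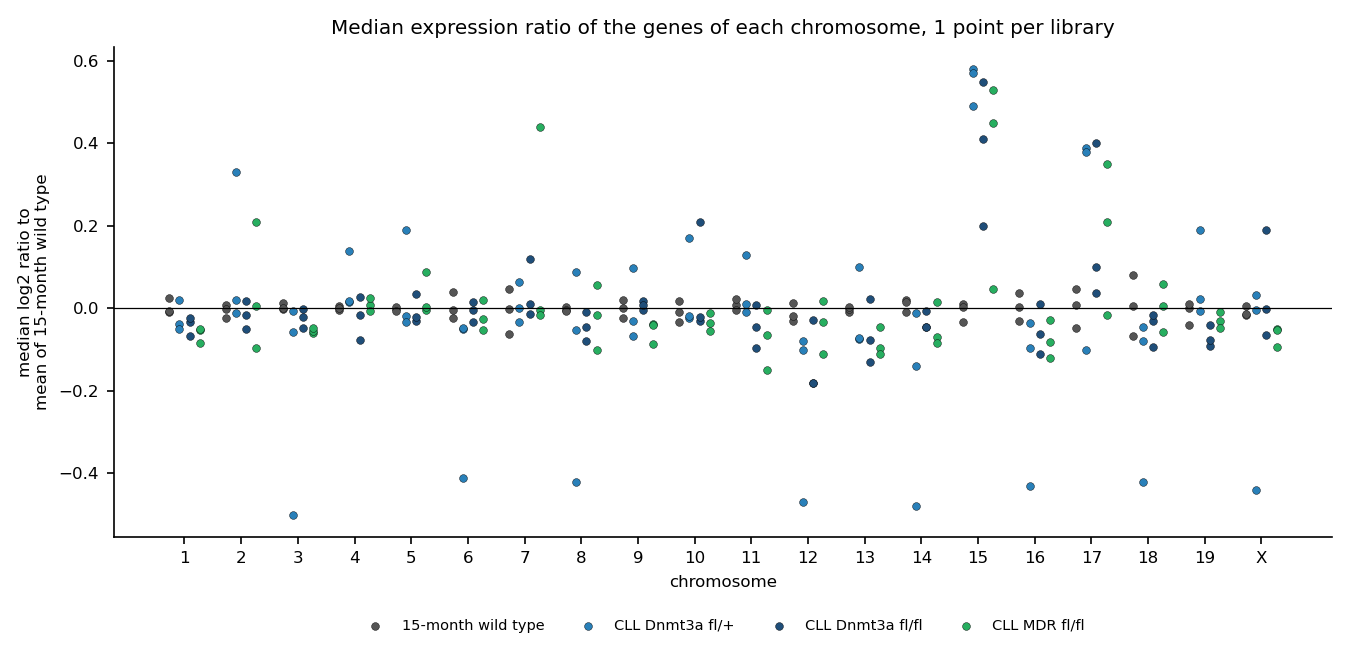
Median log2 ratio to the 15-month wild type mean (vertical axis) of the genes of each chromosome (horizontal axis) in the 9 CLL libraries and the 3 wild type libraries, each wild type library set against the other 2. On chromosome 15 the CLL libraries lie between 0.047 and 0.58.

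The CLL groups were also compared with each other. By the labels CLL Dnmt3a fl/+ came from younger mice than the other CLL groups. Genotype therefore cannot be separated from age in either comparison with CLL Dnmt3a fl/+. CLL Dnmt3a fl/fl had more Grb7, an adaptor of receptor kinases (61.6 ± 21.9 against 1.44 ± 0.837 CPM; 5.42 ± 0.511, adjusted p = 0.00403) than CLL Dnmt3a fl/+. It had more Stat4 (20.8 ± 8.4 against 2.76 CPM; 2.91 ± 0.33, adjusted p = 0.016) and more Lef1 (19.3 ± 11.7 against 0.277 CPM; 6.11 ± 0.781, adjusted p = 0.0272), and less Amacr, a racemase of fatty acid oxidation (14.3 ± 2.14 against 56.8 ± 10.2 CPM; −1.99 ± 0.257, adjusted p = 0.0272). Apobr (4.89 ± 0.46, adjusted p = 0.00403) and Slc23a3 (5.74 ± 0.733, adjusted p = 0.0272) complete the 6 calls and were chosen after their values were seen. Against CLL MDR fl/fl, CLL Dnmt3a fl/fl had more Dleu2 (2.29 ± 0.342), more Stat4 (2.78 ± 0.328, adjusted p = 0.0032) and more Lef1 (5.80 ± 0.768), and less Cadps2, a factor of vesicle release (0.682 against 18.5 ± 2.77 CPM; −4.76 ± 0.359, adjusted p = 0.000625). Of 19 TP53 targets 3 were lower, Bbc3 (−2.44) among them, 0 higher and 16 not past (0 up and 5 down adjusted over the list alone; camera adjusted p = 0.00508, adjusted p = 0.496 with an estimated correlation). CLL Dnmt3a fl/+ had less Klf2 than CLL MDR fl/fl (35.4 ± 11.5 against 531 ± 363 CPM; −3.91 ± 0.565), less Cadps2 (−5.04 ± 0.365) and less Mreg (−5.64 ± 0.699). In that comparison 5 of 30 genes of B cell receptor signalling were higher, such as Nfatc1 (1.79), 1 lower, Prkcb (−1.11), and 24 not past (10 up and 2 down adjusted over the list alone; camera adjusted p = 3.68e-05, adjusted p = 0.343 with an estimated correlation).

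The test called 6 genes between the Dnmt3a CLL groups (5 higher and 1 lower), 273 between fl/fl and MDR (73 and 200) and 514 between fl/+ and MDR (157 and 357). All 6 of the first were lost in at least 1 fit. That count was 0 and 1 without CLL Dnmt3a fl/+ replicates 1 and 3 and 3 without CLL Dnmt3a fl/fl replicate 1 or 2. For fl/fl against MDR it was 95 and 129 without CLL Dnmt3a fl/fl replicates 1 and 2, and 495 without CLL MDR fl/fl replicate 3. With these groups fitted alone it was 0 (edgeR), against 3025 genes at an unadjusted p under 0.05, 1365 calls by DESeq2 and 275 by limma-voom in the 12-library fit. Counts for fl/+ against MDR were 253 and 296 without CLL Dnmt3a fl/+ replicates 1 and 2, 314 and 930 without CLL MDR fl/fl replicates 1 and 3, and 60 with these groups fitted alone.

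Changes seen at 4 months were then looked for in CLL, whose fit shares no library with theirs. Of the genes higher in B1 Dnmt3a fl/fl, 32 were also higher in CLL Dnmt3a fl/fl where independent lists would share 24, and of those lower 49 were also lower where 55.7 would be shared. No B1 set passed fry in a CLL comparison. Camera called only the set lower in B1, which was higher in CLL Dnmt3a fl/+ (median log2 fold change 0.167, adjusted p = 0.0375; adjusted p = 0.946 with an estimated correlation). Genes higher in the average of B1 and B2 shared 24 with those higher in CLL Dnmt3a fl/fl against 11.4 for independent lists. Genes lower in that average shared 26 with those lower in CLL Dnmt3a fl/fl (25.1 for independent lists). With those lower in CLL MDR fl/fl they shared 36 (18.8). In the opposite direction, they shared 62 with genes higher in CLL Dnmt3a fl/+ (35.7). Excess sharing was thus not limited to Dnmt3a CLL or to the same direction.

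CLL comparisons shared many calls with each other. CLL Dnmt3a fl/fl and fl/+ had 333 genes higher and 436 lower in both, where independent lists would share 26.1 and 31.5. The fl/fl and MDR groups had 233 and 167 (17.6 and 15.0), and fl/+ and MDR 306 and 211 (29.6 and 23.3). In all 3 groups 201 genes were higher and 129 lower. The covariance of log2 fold changes across genes was 1.31, 1.08 and 1.30 in that order, against 0.263, 0.261 and 0.262 in 20 simulations of unchanged groups with the same controls. The correlation was 0.681, 0.57 and 0.652, against 0.49, 0.491 and 0.492 simulated. The simulated controls had the spread pooled over all 4 groups. Real wild type replicates differed less (chi-square per degree of freedom 81.5 to 205) than CLL replicates (297 to 1450). The simulated values can therefore overstate what shared controls bring. Part of the excess may come from the shared controls, which are too few to split.

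Shares of immunoglobulin V segments were compared between libraries. They are shares of RNA counts, which cannot tell many cells from high expression per cell, so evenness of the cells was not measured. In 15-month wild type the leading Ighv segment held 10.5% ± 4.7 (SD, n = 3) of Ighv counts, and in the 9 CLL libraries 58.9% ± 25.4, a difference of 48.5 percentage points (exact two-sided permutation p = 0.0136). Ighv1-66 held 91.2% (95% interval 91.2 to 91.3) in CLL Dnmt3a fl/+ replicate 3, Ighv7-4 89.0% (88.9 to 89.0) in CLL Dnmt3a fl/fl replicate 2 and Ighv5-9 82.2% (82.2 to 82.3) in CLL MDR fl/fl replicate 1. The lowest CLL share was 13.3% (13.2 to 13.4), Ighv1-55 in CLL Dnmt3a fl/fl replicate 3, a library with both Xist and Ddx3y transcripts. The leading Igkv segment held 74.2% ± 22.1 in CLL and 8.17% ± 2.4 in wild type (exact two-sided permutation p = 0.00455, the smallest these numbers allow). At 4 months Ighv11-2 led all 6 B1 libraries, with 44.2% ± 5.05 in B1 wild type and 54.5% ± 22.6 in B1 Dnmt3a fl/fl, while B2 wild type had 5.91% ± 0.192 and B2 Dnmt3a fl/fl 6.48% ± 0.622. The leading Igkv segment held 33.1% ± 12.7 in B1 wild type (22.3 to 47.1) and 59.7% ± 6.91 in B1 Dnmt3a fl/fl (54.0 to 67.4), ranges that do not overlap. It was Igkv4-91 in 5 of these 6 libraries and Igkv12-89 in B1 Dnmt3a fl/fl replicate 3. In B2 the Igkv shares were 6.22% ± 0.241 and 7.62% ± 2.85. With 3 libraries against 3 the smallest exact p is 0.1. Each CLL group reached it for the leading Igkv segment against 15-month wild type. For the leading Ighv segment CLL Dnmt3a fl/+ and MDR reached it and CLL Dnmt3a fl/fl did not (exact p = 0.2). Without 15-month wild type replicate 1 or 3 the Ighv test over 9 CLL libraries gave an exact p of 0.0545.

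**Figure D4:**
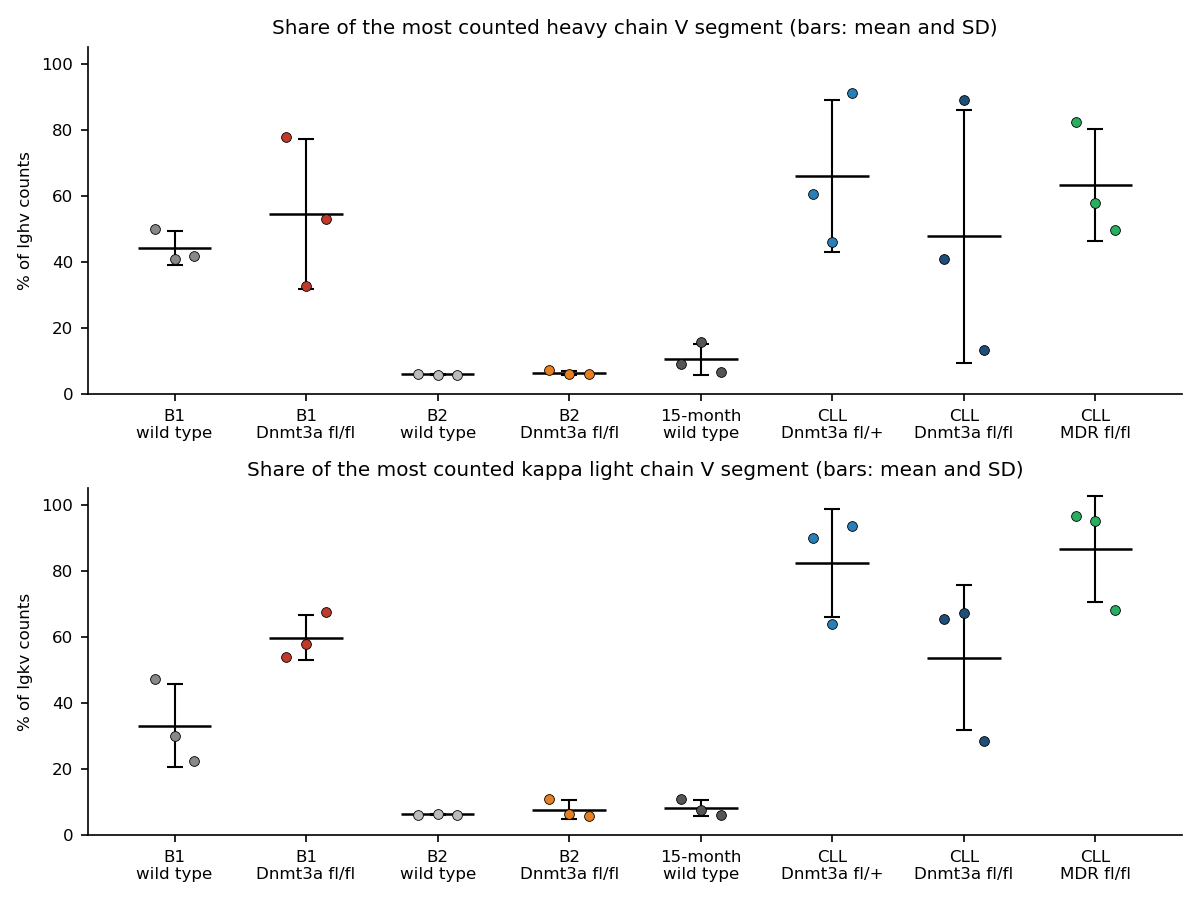
Share of the leading Ighv and Igkv segment, in percent of all Ighv or Igkv counts (vertical axis), in each of the 24 libraries by group, with points for libraries and bars for group mean and SD. Leading Ighv shares averaged 10.5% in 15-month wild type and 65.9%, 47.7% and 63.2% in CLL Dnmt3a fl/+, fl/fl and MDR fl/fl.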

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

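The fit with sex as a term and the fits without the pair of B2 libraries with broad background were chosen after seeing the data. The effect of Dnmt3a loss differed between B1 and B2 by an edgeR test of the difference itself for 856 genes, each printed value below being the log2 fold change in B1 minus that in B2. The genes listed are those named for B1, B2 or the difference, without those named for the mean alone, such as Fam43a. Of these, higher in B1 relative to B2 were Hspa1a (9.10), Hspa1b (8.37), Fos (4.62), Krt8 (2.85), Fcer1g (2.62), Cd69 (2.33) and Dnajb1 (2.29). Lower were Ckb (−3.51), Ercc2 (−3.29), Cpm, the gene of carboxypeptidase M (−2.85), Ssbp4 (−2.59), Acvr1b (−2.57), Fam234b (−2.44), Ngfr (−2.39), Bhlhe40 (−2.37), Ccl5 (−2.34), Thop1 (−2.31), Pax5 (−2.13), Fcer2a (−2.07), Lbh (−2.01), Icosl (−1.75), Lfng (−1.75), Mcm2 (−1.30), Dtx2 (−1.17), Ipo4 (−1.16), Hyou1 (−1.13), Ciita (−1.05), Spib (−1.04), Mybbp1a (−1.001), Inpp5d (−0.88), Farsa (−0.85) and Plcg2 (−0.70). The count was 543 without B1 Dnmt3a fl/fl replicate 3 and 507 and 477 without B2 Dnmt3a fl/fl replicates 1 and 2. With sex as a term 41 genes were called higher and 322 lower in B1 relative to B2. Only B1 Dnmt3a fl/fl replicate 3 and B2 wild type replicate 3 had more Xist than Ddx3y at 4 months. Their genotypes are opposite, so sex is not balanced over this difference and may account for part of it. Without 1 library Fos lost its call in 8 of 12 fits (adjusted p up to 0.133, without B2 Dnmt3a fl/fl replicate 2), Krt8 in 6 (up to 0.0812, without B2 wild type replicate 1), Dnajb1 in 6 (up to 0.0709, without B1 wild type replicate 1) and Cpm in 10 (up to 0.111, without B1 Dnmt3a fl/fl replicate 3). Fam234b lost its call without the pair of B2 libraries with broad background (adjusted p = 0.0746).

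The pattern to weigh is that 2261 genes were called in B1 and 2 in B2, while groups did not overlap in 32.6% and 18% of tested genes. Broad background in B2 wild type replicate 3 (olfactory and vomeronasal receptor genes at 360 CPM against 39 and 32.8 in the other B2 wild type libraries) could have raised the spread. All groups of the fit share its estimate of spread, so a raised spread would lower the B1 calls as well. The fit without that library called 13 genes in B2. Both points argue against its background as the whole cause. Sex could have added calls in B1, where Dnmt3a fl/fl replicate 3 alone carried Xist, but 1328 genes were still called without that library, the lower of this fit and the fit with sex as a term, which argues against sex as the main source. A difference between the subsets and cells of other types stay open, since T cell markers had a median of −2.06 in B2, and Dnmt3a itself differed by 0.22 between the effects (adjusted p = 0.545).

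Other splits of the same libraries were counted for each test across genes. For the mean over B1 and B2, 1 of 100 splits, the real one, gave 1042 genes, the highest other being 896. Chance can be excluded for a genotype effect in at least 1 of B1 and B2, but not for an effect in both. For the difference between B1 and B2, 2 of 100 splits gave as many genes as the real 856, the highest other being 869. The splits exchange genotypes within B1 and within B2, so they stand for no genotype effect in either. A genotype effect in B1 alone can give this share and is itself a difference between the effects. Splits of this kind cannot test whether 2 real effects are equal, so they do not decide on chance for the difference. For the mean and the difference, the 8 drawn splits that keep the B1 genotypes gave at least 393 and 280 genes. The 91 that exchange B1 libraries gave at most 2, which points to the B1 genotype as the structure behind both counts. For all CLL against wild type 1 of 100 splits gave 2101 genes, the highest other being 704, and chance can be excluded. The remaining tests have 10 splits each, too few for a share under 0.05. Real counts and highest others were 2261 and 2 for B1, 2 and 1 for B2, 7142 and 0 for B1 against B2 wild type, 1072 and 0 for CLL Dnmt3a fl/fl, 1728 and 0 for CLL Dnmt3a fl/+, 991 and 0 for CLL MDR fl/fl, 6 and 0 between the Dnmt3a CLL groups, 273 and 0 for fl/fl against MDR and 514 and 0 for fl/+ against MDR.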

How the results depend on the processing

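The settings without the pair of B2 libraries with broad background (B2 wild type and Dnmt3a fl/fl, replicate 3 of each), without the pair of CLL libraries that stand apart (CLL MDR fl/fl replicate 2 and CLL Dnmt3a fl/fl replicate 3), without chromosomes 15 and 17 and with sex as a term were chosen after seeing the data. The direction with more calls turned in 5 comparisons, as given below, and no tested value of a whole comparison changed sign. Of the values, 375 kept their side of the threshold or stayed near the main value, 121 counts moved by over 1.5 times, 11 values passed and 4 no longer passed. For named genes 4533 values kept their call, 760 lost it and 27 changed sign. Where no reason is stated below, the cause was not tested.

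With a fold change of at least 2 as well, which is stricter by construction, the counts were 640 (B1), 1 (B2), 124 (mean), 516 (difference), 3675 (B1 against B2 wild type) and 1380 (all CLL). Without a filter, so with more genes tested, they were 1435 (B1), 1 (B2) and 517 (mean). Fitting the groups of a comparison alone gave 1370 (B1), 3111 (CLL Dnmt3a fl/fl), 2938 (CLL Dnmt3a fl/+), 175 (CLL MDR fl/fl), 13 (fl/fl against fl/+), 60 (fl/+ against MDR) and, for fl/fl against MDR, 0 (edgeR; 3025 genes at an unadjusted p under 0.05 in the main test, 1365 calls by DESeq2 and 275 by limma-voom). A fit of all 24 libraries gave 783 (B1), 140 (mean), 232 (difference), 2954, 3733, 3192 and 4208 (CLL Dnmt3a fl/fl, fl/+, MDR and all CLL), 380, 1601 and 1875 (fl/fl against fl/+, fl/fl against MDR, fl/+ against MDR) and 0 in B2 (edgeR; 1812 genes at an unadjusted p under 0.05 in the main test, 196 calls by DESeq2 and 2 by limma-voom). In that fit Dnmt3a was −0.70 in B1 and no longer passed, and passed at −0.70 (CLL fl/fl), −0.57 (CLL fl/+) and −0.71 (fl/fl against MDR). The DESeq2 Wald test gave 196 (B2), 2035 (mean), 1680 (difference), 2605, 3306, 2777 and 3638 (the CLL groups and all CLL), 472, 1365 and 1595 (between CLL groups), and Dnmt3a passed at −0.93 in B2 and −0.34 in B1 against B2 wild type, where the strict filter gave −0.38 and a pass. Upper-quartile factors put 23.9% of the calls of the difference higher in place of 13.1%, and no other scaling moved a share by over 10 percentage points. The direction with more calls turned from higher to lower in CLL MDR fl/fl (568 and 423) with limma-voom (398 and 534), in the groups alone (40% higher) and without 15-month wild type replicate 1 (43 and 56), 2 (100 and 122) or 3 (49 and 61). In all CLL it turned from lower to higher (921 and 1180) with DESeq2 (2019 and 1619). In the CLL Dnmt3a fl/fl and fl/+ comparisons and in B1 against B2 wild type 46.6%, 48.7% and 49.5% of calls were higher, and 9, 10 and 10 settings turned the majority, with up to 56.4%, 56.4% and 55% higher, so these have no stable majority.

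Replicate numbers do not pair the libraries: same-numbered libraries correlated in their deviations from group means by at most 0.077 (median 0.0014) in the CLL fit and 0.057 (median −0.015) in the 4-month fit. With the replicate number as a block the counts were 582, 1081 and 425 (CLL Dnmt3a fl/fl, fl/+ and MDR), 3, 132 and 316 (fl/fl against fl/+, fl/fl against MDR, fl/+ against MDR), and no other count moved by over 1.5 times.

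With 4-month B1 wild type as control the counts were 5095, 5552 and 4730 (CLL Dnmt3a fl/fl, fl/+ and MDR) and with B2 wild type 5124, 5654 and 6289. Against B1 wild type these log2 fold changes changed sign. In CLL Dnmt3a fl/fl they were Rflnb 0.84, Fcer2a 0.0554, Nrarp 1.39, Myc −0.10, Cd9 −0.12, Lgals1 −1.35, Icosl 0.87 and Cd68 −0.0324. In CLL Dnmt3a fl/+ they were Rflnb 0.34, Pxdc1 0.00576, Emid1 1.45, Nrarp 0.29, Fcer2a 1.08, Cd9 −0.40, Lgals1 −1.96, Bach2 0.54 and Mcm6 −0.10. In CLL MDR fl/fl they were Rflnb 0.85, Emid1 1.19, Fcer2a 0.50, Myc −0.24, Lgals1 −0.52, Cd9 −0.74, Ccnd2 −1.58 and Irf7 1.201. Against B2 wild type Klf2 was 0.44 in CLL Dnmt3a fl/fl, and without 15-month wild type replicate 3, the only wild type library of that age with Y-linked transcripts, Uty was 3.10 in all CLL, with −5.77 without replicate 2.

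Without the pair of B2 libraries with broad background the mean gave 208 and the difference 481, and with sex as a term the difference gave 363. Without the pair of CLL libraries that stand apart the counts were 2019, 3020, 1680 and 3620 (CLL Dnmt3a fl/fl, fl/+, MDR and all CLL) and 29 (fl/fl against fl/+), and Dnmt3a passed at −1.03 in CLL Dnmt3a fl/fl and −0.55 in all CLL.

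Leaving out 1 library at a time gave 1328 to 2091 genes in B1, 1 to 13 in B2, 260 to 960 for their mean, 477 to 1003 for their difference and 6095 to 6763 for B1 against B2 wild type. It gave 277 to 934 for CLL Dnmt3a fl/fl, 594 to 1399 for CLL Dnmt3a fl/+, 99 to 1491 for CLL MDR fl/fl, 661 to 3314 for all CLL, 0 to 5 for fl/fl against fl/+, 95 to 495 for fl/fl against MDR and 253 to 930 for fl/+ against MDR. Dnmt3a ran from −0.79 to −0.58 in B1 and from −1.03 to −0.57 in CLL Dnmt3a fl/fl, where it passed without replicate 3 only, and the difference in the leading Ighv share from 46.5 to 51.1 percentage points, with an exact p of 0.0545 in 2 of 3 fits. Named genes that kept their call in every such fit were Rflnb, Lrrk2, Pxdc1, Cd5, Cd9, Arid3a, Lgals1, Bach2, Creld2 and Srm in CLL Dnmt3a fl/fl, and Rflnb, Gpr171, Lef1, Dleu2, Lgals1, Tbrg4, Cdkn1a and Bbc3 in CLL MDR fl/fl.

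With an estimated correlation camera called 2 lists in B1 against B2 wild type and 0 in each other comparison, where camera at its preset correlation called 4 to 12. Fry called 0 lists in B2, 4 for the difference, 20 for B1 against B2 wild type, 7 in CLL MDR fl/fl, 0 for fl/fl against fl/+, and 2 each for fl/fl and fl/+ against MDR. The 200 genes of smallest p in each direction were also tested in place of the called genes, by camera at its preset correlation only. Those higher in B1 had a median of 0.159 in CLL Dnmt3a fl/fl and passed. Those lower in B1 had 0.0674 in CLL Dnmt3a fl/+ and no longer passed, and −0.181 in CLL MDR fl/fl and passed.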

Other observations

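The test of Myc against its chromosome, the tests of basophil and mast cell genes, and the setting without chromosomes 15 and 17 were chosen after seeing the data.

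In B1 Dnmt3a fl/fl the low-affinity nerve growth factor receptor Ngfr fell from 41.9 ± 23.4 to 7.46 ± 1.55 CPM (n = 3; −2.49 ± 0.321, edgeR adjusted p = 0.000347), while Ctla4, which dampens activation, rose from 33.8 ± 15.4 to 111 ± 20.5 CPM (1.72 ± 0.387, adjusted p = 0.0117). Of 23 plasma cell genes 3 rose, among them Mzb1 (0.52 ± 0.127) with Jchain, 2 fell, such as the chaperone Hyou1 (−1.19 ± 0.188), and 18 did not pass (6 up and 2 down adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.628 with an estimated correlation). Mzb1 lost its call without B1 wild type replicate 1 (adjusted p = 0.0593), B1 Dnmt3a fl/fl replicate 2 (0.066) or replicate 3 (0.0722). In CLL MDR fl/fl 2 of 15 BCL2 family genes rose, 0 fell and 13 did not pass (4 up and 0 down adjusted over the list alone; camera adjusted p = 0.00887, adjusted p = 0.218 with an estimated correlation). B1 wild type libraries had lower interferon response genes than B2 wild type, with 17 of 30 lower, such as Oasl1 (−4.83) and Irf7 (−3.03), 3 higher and 10 not past (3 up and 18 down adjusted over the list alone; camera adjusted p = 0.000148, adjusted p = 0.373 with an estimated correlation).

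Genes of chromosome 15 stood higher as a whole in 8 of 9 CLL libraries, with medians of 0.58, 0.49 and 0.57 in CLL Dnmt3a fl/+, 0.41, 0.55 and 0.20 in CLL Dnmt3a fl/fl, and 0.45 and 0.53 in CLL MDR fl/fl, but 0.047 in its replicate 2; 11.5% of genes higher in all CLL lay there, with 3.77% of genes tested. After removal of the trend with GC content and length the mean stayed at 0.43, which argues against these as the source. An extra copy of the whole chromosome may account for it: in libraries with a median above 0.3 the lower, middle and upper parts of the chromosome were all raised, the lowest at 0.28, though expression alone does not count copies. The adjusted p over 20 chromosomes was 0.091 by the permutation test. With 1 chromosome shifted alone it cannot fall below that value, so it does not decide the question. Myc, which lies there, exceeded its chromosome by 1.04 ± 0.054 (SE, n = 9). All 9 ratios share the same wild type mean, so this SE leaves out the spread of the control and is too small. The size of the excess still argues against the chromosome as the whole rise of Myc. Age is not the whole cause, since CLL Dnmt3a fl/fl and CLL MDR fl/fl share the 15 months of their control, and a B1-like origin stays open for Myc, which did not rise against B1 wild type.

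Other chromosomes shifted in some CLL libraries. Chromosome 17 had medians of 0.39 and 0.38 in CLL Dnmt3a fl/+ replicates 1 and 2, 0.40 in CLL Dnmt3a fl/fl replicate 2, and 0.21 and 0.35 in CLL MDR fl/fl replicates 1 and 3, with at most 0.10 in the other 4. The mean over CLL libraries was 0.19 ± 0.19 (SD, n = 9). A permutation test with the same unequal references as for chromosome 15 gave p = 0.132 (adjusted p = 0.705 over 20 chromosomes), a p that is not exact. Chromosome 7 stood at 0.44 in CLL MDR fl/fl replicate 1. In CLL Dnmt3a fl/+ replicate 1, the library with the highest value on chromosome 15, chromosome 2 stood at 0.33 and chromosomes 3, 6, 8, 12, 14, 16, 18 and X at −0.50 to −0.41, so shifts in that library were not limited to chromosome 15.

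Cd200r3 (8.76), Cyp11a1 (6.24) and Hdc (6.02) were called higher in CLL Dnmt3a fl/fl, of which Cd200r3 alone is among its 6 largest rises and the others were chosen after their values were seen. The sum of 7 basophil and mast cell genes (Mcpt8, Prss34, Cpa3, Ms4a2, Fcer1a, Gata2 and Il4, none of them called) was 752 CPM in CLL Dnmt3a fl/fl replicate 3 and 0.277 to 65.2 in the other 8 CLL libraries, and Cd200r3 followed it (Spearman 0.767, exact permutation p = 0.0214, adjusted p = 0.0642 over 3 genes; Pearson on log2 values 0.885, p = 0.00081, and 0.745 without the 2 libraries farthest from the median), so such cells, which B cell isolation should remove, may be its source. For the histamine enzyme Hdc, 2 of the other 8 libraries held over 5 times what their marker sum would bring, and its source stays open (Spearman 0.567, exact permutation p = 0.121; Pearson 0.74, p = 0.0297, and −0.254 without the 2 farthest, so the relation rests on these). Cyp11a1 was that far above in 7 of the other 8 (Spearman 0.183, exact permutation p = 0.644; Pearson 0.439, p = 0.239, and −0.418 without the 2 farthest), such as 511 CPM beside a marker sum of 2.50 in CLL Dnmt3a fl/+ replicate 1, which argues against these cells as its source. Both tallies include CLL MDR fl/fl replicate 2, where neither gene was raised. Its Hdc was 1.85 CPM and its Cyp11a1 0.745, against 1.02 to 3 and 0.106 to 3.99 in 15-month wild type.

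Sex-linked transcripts differed between replicates of a group. In 4-month mice Xist stood at 207 CPM in B2 wild type replicate 3 and 106 CPM in B1 Dnmt3a fl/fl replicate 3, and under 1 CPM in the other 10 libraries. CLL Dnmt3a fl/fl replicate 3 held both Xist (82.3 CPM) and Ddx3y (69.5 CPM). A mixture of mice in that library was not tested, and it would lower the leading Ighv share there, 13.3%, and bear on the exact p of 0.2 for its group. Both transcripts were low in others: CLL Dnmt3a fl/+ replicate 1 (1.24 and 0.264 CPM), CLL Dnmt3a fl/fl replicate 2 (0.481 and 3.05 CPM) and CLL MDR fl/fl replicate 2 (0.255 and 1.04 CPM). Olfactory and vomeronasal receptor genes reached 360 CPM in B2 wild type replicate 3, 147 in B2 Dnmt3a fl/fl replicate 3 and 127 in CLL Dnmt3a fl/+ replicate 2, and 18.7 to 49.7 CPM in the other 21 libraries. Of 43 genes tested within 10 megabases of Dnmt3a 2 were called in B1 (4.65%, against 14.6% of all genes).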
